A study of Homo sapiens with 160 samples.

How the data were processed

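The series holds 160 human samples of CD56hi, CD56dim and CD56neg NK cells and ILCs sorted from blood mononuclear cells of people in 4 HIV-1 groups, 10 samples for each of 16 combinations. Per the labels' protocols, RNA was extracted with Trizol and polyadenylated RNA was made into libraries by CEL-Seq2, a method that tags the 3' ends of transcripts with a sample barcode and a molecular identifier. The submitters' processing notes name cutadapt 2.9, STAR 2.6.1, UMI-tools 1.1.2, SAMtools 1.9 and the build hg38. The counting tool, the annotation and the use of strand are not given in the sources used here. The authors deposited estimated counts of deduplicated reads per gene in 1 table of 60591 genes and 160 libraries, made before deposition without scaling to library size. The unit rests on the wording of the deposited table and on its values, and 49.6% of the values above 0 lie within 0.001 of a whole number.

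Each column name of the deposited table gives a population and a barcode number, 1 to 40 for CD56hi and CD56neg libraries and 41 to 80 for CD56dim cells and ILCs. No label holds these barcode numbers, so no column could be given an HIV-1 group or replicate. The planned comparisons, which were between HIV-1 groups within each population and between populations within 1 HIV-1 group, were not analysed here. In their place 40 libraries of each population were compared over the HIV-1 groups, and a comparison of CD56hi with CD56neg cells was added because these share barcodes. These comparisons and their alternative settings were chosen after the data had been seen. The edgeR and camera tests, the gene lists and the rule for naming genes were fixed before the data were examined, while several tests across libraries in the closing section were chosen later, as stated there. Population averages over the 4 HIV-1 groups can hide or blend differences between those groups. The labels do not say whether the 10 samples of a group came from 10 people or whether 1 person gave several populations, so p-values measure the spread between libraries, taken as independent.

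Counts were rounded to whole numbers and 511 rows of Y-linked genes, XIST and TSIX were left out of the tests. Genes were kept by filterByExpr of edgeR 4.0.16 with the population as group and a minimum count of 10, which left 11224. Library sizes were scaled by TMM, whose factors ran from 0.827 to 4.61. A single model with 4 population means was fitted to 160 libraries with glmQLFit and tested with glmQLFTest in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. The standard error of a log2 fold change was its size divided by the square root of F. Levels are log2 CPM (counts scaled to library size) with a prior count of 2, and fold changes come from the fitted model. The size of a large fold change is uncertain where 1 or both populations lie near 0.88, the level of a library without a count. Examples are KIR2DL4 in ILCs (23 counts summed over 40 libraries), CCR7 in CD56dim cells (25) and LAG3 in CD56hi cells (32). Lists were tested on limma-voom values (limma 3.58.1) with camera at a preset correlation of 0.01 between genes, adjusted over 25 lists per comparison, and again with an estimated correlation and with fry. Of 27 lists, red cell markers (0 members tested) and haematopoietic progenitor markers (1 tested) were too small to test. Counts of list members are of those tested, which for some lists are few. Tested were 4 of 14 ILC2-associated genes, 4 of 14 B cell and plasma cell markers and 4 of 12 dendritic cell markers. Of platelet markers 3 of 13 were tested, and of KIR genes 7 of 16.

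Genes were named by the rule fixed before the data were examined, carried over to the comparisons over all HIV-1 groups. It took the 10 highest and 10 lowest log2 fold changes past the threshold with a mean of at least 5 log2 CPM (3 and 3 for CD56hi against CD56neg cells), AREG, MYC, RUNX3 and TCF7, and up to 3 members of each list called by camera. The rule leaves out pseudogenes, HLA genes, KIR genes outside their list, antigen receptor segments outside the marker lists and genes without a symbol. Gene identifiers matched GENCODE 29 for 58408 rows, and coordinates are those of GENCODE 29 on GRCh38. KIR genes, XCL1 and XCL2, CCL4, LGALS9B, NPIPB12, TRBC1 and TRBC2, and KLRC1 have near-identical copies, so their counts are uncertain. Of 145 named genes, 31 overlap another protein-coding gene, including TCF7, RABGGTB, AP4B1, FGFBP2, PTGDS, RPL36, RPS28 and TYMS, and reads in the overlap could not be told apart.

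Library totals had a median of 850764.5 counts, and 9 libraries held under 100000 (2 of CD56dim cells, 1 of CD56neg cells and 6 of ILCs). The mitochondrial share was 8.47% ± 1.90 in CD56hi cells, 9.23% ± 1.60 in CD56dim cells, 9.52% ± 2.42 in CD56neg cells and 11.5% ± 3.00 in ILCs (SD, n = 40 each). No pair of libraries had identical counts. The highest correlation between any pair was 0.962, and the lowest chi-square per degree of freedom among the 20 most similar pairs was 4.96, so none was treated as a repeat.

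The steps were tested on simulated counts for 11224 genes drawn from the real means and library sizes with a dispersion of 0.25, with 200 genes changed. For CD56hi against CD56dim cells edgeR recovered 41.8% of the genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold, with 11 false calls among 170. For ILCs against CD56hi cells it recovered 31.3%, 94.0% and 100%, with 10 false calls among 160. A planted list of 20 genes raised 1.5-fold was called by camera in each of the 5 simulated comparisons, and 0 of 40 random lists had an unadjusted p below 0.05 in each. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera falsely calls lists of correlated genes, such as ribosomal protein genes (estimated correlation 0.628 for CD56hi against CD56dim cells). Apart from the 200 changed genes, all populations were drawn from 1 mean profile, whereas the real comparisons called 31.33% to 56.25% of genes. The share of false calls under such broad differences, where scaling matters more, was not tested.

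Alternatives were RLE factors, no low-count filter, libraries under 100000 counts left out, every library thinned to 100000 counts, the barcode number as a block, limma-voom with quality weights and DESeq2 1.42.0. A further one left out, in each population, the 10 libraries with the highest share of T cell markers and the 10 with the highest share of monocyte and neutrophil markers (13 of CD56hi cells, 15 of CD56dim cells, 18 of CD56neg cells and 19 of ILCs). The labels name no batch. No search for single outlying libraries was made, since the planned one was for groups of 10 and not of 40. Tests across libraries used Python 3.11.15 with scipy 1.17.1, libraries of at least 100000 counts and 100000 permutations, two-sided.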

Results

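Bulk RNA was profiled from 4 lymphocyte populations sorted from human blood. CD56 (NCAM1) is an adhesion molecule whose surface level divides natural killer (NK) cells into CD56hi, CD56dim and CD56neg cells. Innate lymphoid cells (ILCs) are related lymphocytes that make cytokines and lack rearranged antigen receptors. The labels list 160 samples in 16 groups of 10, which cross the 4 populations with 4 HIV-1 groups: people without the virus, viremic people, people on antiretroviral therapy and spontaneous controllers. The count table identifies the population and a barcode number of each of its 160 libraries, and no HIV-1 group, so comparisons between HIV-1 groups were not analysed here. Each population was therefore compared over its 40 libraries with the 4 HIV-1 groups together, a choice made after the table had been seen. Library totals ran from 7379 to 6982001 counts, with a median of 1861804.5 in CD56hi cells, 1025229 in CD56dim cells, 591441.5 in CD56neg cells and 483683.5 in ILCs.

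Whole-transcriptome profiles set ILCs and CD56dim cells apart from each other, while CD56neg cells overlapped the other populations on the first principal component. Across 4491 well-expressed genes, which are not independent replicates, the mean profiles of CD56dim and CD56neg cells were the closest pair (Spearman rho = 0.908) and those of CD56dim cells and ILCs the most distant (rho = 0.682). The first principal component held 16.7% of the variance over the 151 libraries with at least 100000 counts. It placed CD56dim cells at −25.8 ± 3.48 (SD, n = 38) and ILCs at 39.8 ± 18.4 (SD, n = 34), with CD56hi cells at −3.76 ± 8.80 (SD, n = 40) and CD56neg cells at −5.76 ± 13.0 (SD, n = 39) between them. CD56neg scores on this component ran from −19.0 to 33.8 and so reached into the ranges of CD56dim cells and ILCs. The highest CD56hi score, 38.9, also lay within the ILC range. The second component held 8.14% and spread libraries within populations, with CD56neg cells at −14.3 ± 19.7 (SD, n = 39, lowest −77.3) and ILCs at 12.3 ± 20.9 (SD, n = 34, lowest −86.5). The CD56neg libraries within the ILC range of component 1 (33.8, 27.7 and 26.4) stood at −77.3, −69.7 and −65.9 on component 2. ILC libraries with such scores on component 1 had positive scores on component 2, so the overlap with ILCs was limited to component 1. The third component held 4.75% and placed CD56hi cells at −20.5 ± 7.50 (SD, n = 40), against 9.07 ± 3.45 (SD, n = 38) for CD56dim cells and 3.61 ± 4.72 (SD, n = 39) for CD56neg cells. ILCs stood at 9.80 ± 7.48 there (SD, n = 34), and their range (−18.5 to 19.2) held that of CD56neg cells (−5.89 to 12.3).

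**Figure D1:**
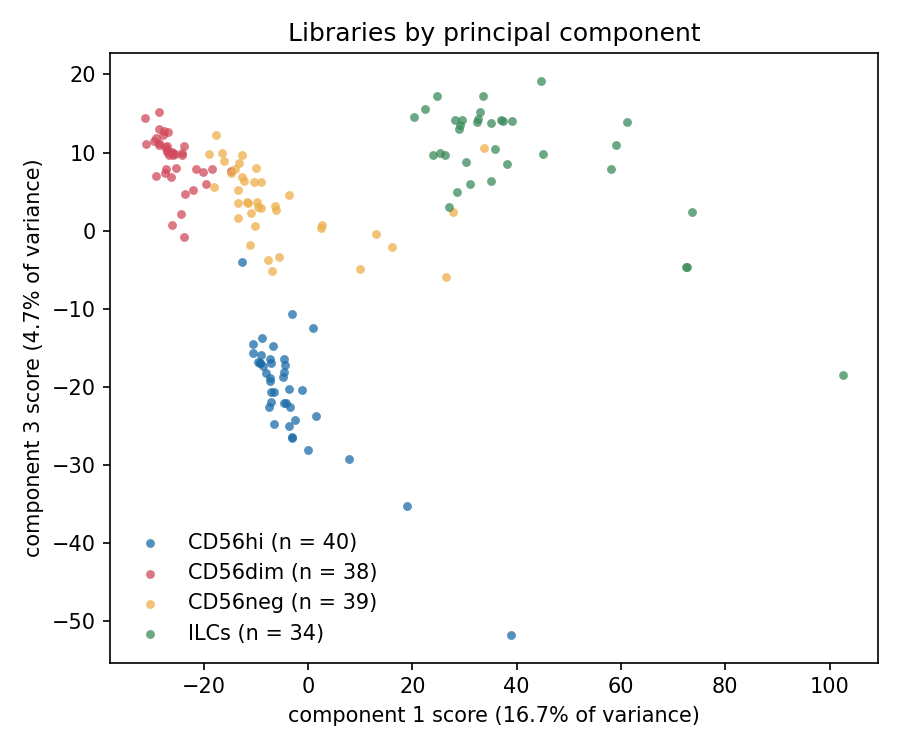
Scores of the 151 libraries with at least 100000 counts on principal components 1 (x axis) and 3 (y axis) of log2 CPM, 1 point per library, coloured by sorted population. ILCs lie at the right (mean 39.8 on component 1), CD56dim cells at the left (mean −25.8), and CD56hi cells low on component 3 (mean −20.5).

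The series title names amphiregulin, an epidermal growth factor family ligand encoded by AREG, as a product of human NK cells. AREG (ENSG00000109321.11, chromosome 4, 74445134 to 74455009, plus strand, GRCh38) was highest in CD56hi cells, at 8.58 ± 1.08 log2 CPM (counts scaled to library size, SD, n = 40). It stood at 6.17 ± 1.33 in CD56dim cells, 5.37 ± 1.196 in CD56neg cells and 5.52 ± 1.87 in ILCs (SD, n = 40 each). CD56hi cells held 4.92-fold more AREG than CD56dim cells (log2 fold change 2.30 ± 0.21 SE, edgeR adjusted p = 1.27e-19) and 9.27-fold more than CD56neg cells (3.21 ± 0.24, adjusted p = 1.77e-26). ILCs held 5.33-fold less than CD56hi cells (−2.41 ± 0.23, adjusted p = 8.55e-19). Between ILCs and CD56dim cells the log2 difference was −0.11 ± 0.24 (adjusted p = 0.704). CD56neg cells held 1.89-fold less than CD56dim cells (−0.91 ± 0.25, adjusted p = 0.00198), a call that ended when each library was thinned to 100000 counts (−0.60, adjusted p = 0.0856).

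TCF7 (ENSG00000081059.20, chromosome 5, 134114711 to 134151865, plus strand), a transcription factor of stem-like and early lymphocytes, was high in CD56hi cells and ILCs and low in CD56dim cells. Its level was 8.53 ± 0.46 log2 CPM in CD56hi cells, 8.19 ± 0.64 in ILCs, 6.05 ± 1.11 in CD56neg cells and 5.001 ± 1.207 in CD56dim cells (SD, n = 40 each). TCF7 was 9.78-fold higher in CD56hi than in CD56dim cells (adjusted p = 1.57e-45), 8.36-fold higher in ILCs (1.98e-41) and 2.22-fold higher in CD56neg cells (7.51e-09). The log2 difference between ILCs and CD56hi cells was −0.23 ± 0.14 (adjusted p = 0.19), and it passed with RLE factors (−0.39, adjusted p = 0.0134), with DESeq2 (−0.37, 0.0411) and without a low-count filter (−0.35, 0.0317). RUNX3 (ENSG00000020633.18, chromosome 1, 24899511 to 24965121, minus strand), a transcription factor of cytotoxic lymphocytes, was abundant in every population. It ranged from 9.54 ± 1.496 in ILCs through 10.58 ± 0.39 in CD56dim and 10.84 ± 0.30 in CD56neg cells to 11.22 ± 0.36 in CD56hi cells (SD, n = 40 each). The wide ILC spread rests largely on 1 library without a RUNX3 count, which also lowers the ILC mean. Libraries without a count likewise widen the spread and lower the mean of AREG in ILCs (3 libraries) and CD56dim cells (1) and of TCF7 in CD56dim cells (2). RUNX3 was 1.55-fold higher in CD56hi than in CD56dim cells (adjusted p = 4.58e-10) and 2.67-fold lower in ILCs than in CD56hi cells (7.15e-32). Its 1.18-fold difference between CD56neg and CD56dim cells (adjusted p = 0.0352) did not pass with RLE factors (0.0761) or DESeq2 (0.0874). MYC (ENSG00000136997.20, chromosome 8, 127735434 to 127741434, plus strand), a growth-promoting transcription factor, was too low for the count filter, with a median of 11 counts per CD56hi library and 1 per CD56dim library. Its level was 3.15 ± 1.28 log2 CPM in CD56hi cells, 1.68 ± 0.74 in CD56dim cells, 1.76 ± 1.19 in CD56neg cells and 3.29 ± 1.52 in ILCs (SD, n = 40 each). In the fit without the filter its log2 fold change was 2.68 for CD56hi over CD56dim cells (adjusted p = 5.39e-18) and 2.93 for ILCs over CD56dim cells (6.94e-18).

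**Figure D2:**
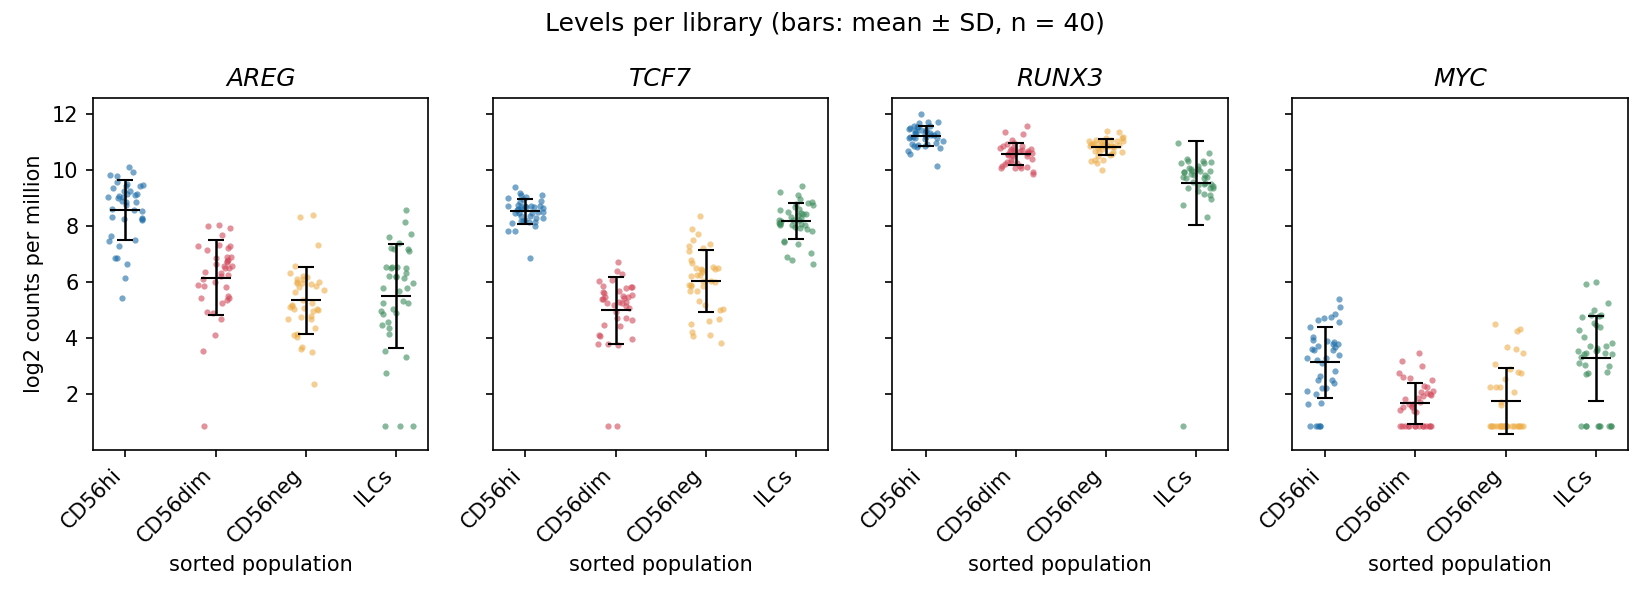
Levels of AREG, TCF7, RUNX3 and MYC (y axis, log2 CPM) in the 40 libraries of each sorted population (x axis). Points are libraries and bars the mean ± SD. AREG is highest in CD56hi cells (mean 8.58), TCF7 is high in CD56hi cells and ILCs (8.53 and 8.19), and points at 0.88 are libraries without a count of the gene.

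CD56hi cells differed from CD56dim cells in the genes that mark the 2 subsets. CD56bright-associated genes rose in 18 of 18 members (18 adjusted over the list alone), with a median log2 fold change of 2.64 (camera adjusted p = 1.11e-27). The chemokine receptor gene CCR7 rose 50.0-fold, the sphingolipid synthesis gene SPTSSB 31.7-fold and the stem cell factor receptor gene KIT 26.0-fold. Stem-like lymphocyte genes rose in 12 of 13 members (12 adjusted over the list alone, camera adjusted p = 5.4e-14), among them NELL2 (25.9-fold) and the interleukin 7 receptor gene IL7R (16.7-fold). Mature CD56dim-associated genes fell in 14 of 15 members (14 adjusted over the list alone, median −2.84, camera adjusted p = 1.13e-23). Their largest declines were in MYOM2 (27.4-fold), the fractalkine receptor gene CX3CR1 (22.9-fold) and AKR1C3 (16.5-fold).

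Cytotoxic effector genes fell in 12 of 17 members and rose in 3 (12 and 3 adjusted over the list alone, camera adjusted p = 1.42e-07). FGFBP2 fell by 13.7-fold, SPON2 by 12.5-fold and the granzyme gene GZMH by 7.53-fold. KIR genes, which encode receptors for HLA class I, fell in 6 of 7 members and rose in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 5.98e-04), with KIR2DS4 6.51-fold and KIR2DL3 5.85-fold lower. Inhibitory receptor genes fell in 6 of 10 members and rose in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00237), led by LAG3 (23.2-fold) and TIGIT (2.64-fold). T cell markers fell in 10 of 16 members (10 fell and 1 rose adjusted over the list alone), CD3D among them by 10.7-fold, but the call was lost with an estimated correlation (adjusted p = 0.227). Cytosolic ribosomal protein genes rose in 59 of 72 members and fell in 3 (60 and 3 adjusted over the list alone, median 0.65, camera adjusted p = 4.12e-28). RPL36 rose 3.31-fold and RPS28 3.20-fold, and the list had adjusted p = 0.0925 with an estimated correlation. Immediate early genes rose in 12 of 25 members and fell in 2 (12 and 2 adjusted over the list alone), led by DUSP2 (2.81-fold) and NFKBIA (2.68-fold), with adjusted p = 0.414 with an estimated correlation. ILC-associated genes rose in 7 of 13 and fell in 4 (7 and 4 adjusted over the list alone), ILC2-associated genes rose in 3 of 4 and fell in 1 (3 and 1), and MYC target genes rose in 12 of 24 and fell in 2 (12 and 2). Those 3 calls were lost with an estimated correlation (adjusted p = 0.247, 0.0865 and 0.316).

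In all, 5877 of the 11224 genes tested differed between CD56hi and CD56dim cells, 3195 higher and 2682 lower in CD56hi cells. The remaining genes with the largest rises were FXYD7 (19.8-fold), the lymphotactin gene XCL1 (18.4-fold), the phosphatase gene DUSP4 (17.6-fold), ANO9 (14.4-fold), SCML1 (13.9-fold) and the nuclear lamin gene LMNA (12.3-fold). The remaining genes with the largest declines were the prostaglandin D synthase gene PTGDS (27.2-fold), BNC2 (18.1-fold), TKTL1 (13.5-fold), the chemokine gene CCL4 (10.8-fold) and NPIPB12 (9.96-fold). Barcodes 1 to 40 marked CD56hi libraries and 41 to 80 CD56dim libraries, so within this comparison a difference between the barcode sets cannot be told apart from the population. The shifts of CD56bright-associated and mature genes also appeared between CD56hi and CD56neg cells, which share a barcode set (18 of 18 higher and 15 of 15 lower, each the same number adjusted over the list alone). Those shifts in CD56hi cells thus do not need a difference between sets. Libraries with the same barcode cannot lie in 1 pool of barcoded libraries, however, so a difference between pools was not excluded in comparisons within a set. With RLE factors the split was 2640 higher and 3328 lower, and with DESeq2 2138 higher and 2842 lower.

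CD56neg cells resembled CD56dim cells more than the other populations did. They had less of the gene that encodes CD56 and more transcripts of genes listed as markers of other blood cells. NCAM1 was 20.8-fold lower (log2 fold change −4.38 ± 0.22 SE, edgeR adjusted p = 1.14e-45), a gene whose product was used in the sort. Monocyte and neutrophil markers rose in 13 of 15 members (14 adjusted over the list alone, median 1.46, camera adjusted p = 3.59e-11), among them the ficolin gene FCN1 (4.38-fold), the lysozyme gene LYZ (4.08-fold) and MNDA (3.72-fold). The list had adjusted p = 0.171 with an estimated correlation. T cell markers rose in 8 of 16 members (8 adjusted over the list alone), with CD8B 4.95-fold and THEMIS 4.91-fold higher, and adjusted p = 0.312 with an estimated correlation. B cell and plasma cell markers rose in 3 of the 4 members tested, of 14 in the list (3 adjusted over the list alone), namely MS4A1 (4.30-fold), IGKC (4.03-fold) and CD74 (2.36-fold). This call held with an estimated correlation (adjusted p = 0.0478). CD74 had counts in 39 of 40 ILC libraries and in all 40 of each other population, so it was not particular to B cells here. IGKC did not pass with limma-voom (adjusted p = 0.0958).

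Genes that are low in adaptive NK cells fell in 6 of 10 members (8 adjusted over the list alone, camera adjusted p = 8.85e-06). The interleukin 18 receptor subunit gene IL18RAP fell by 2.79-fold, KLRC1, which encodes NKG2A, by 2.42-fold and NCR3 by 1.86-fold, with adjusted p = 0.0758 with an estimated correlation. Cytotoxic effector genes fell in 7 of 17 members and rose in 3 (9 and 4 adjusted over the list alone), with SPON2 2.56-fold and the Fas ligand gene FASLG 2.14-fold lower. KIR genes fell in 5 of 7 and rose in 1 (5 and 1 adjusted over the list alone), among them KIR2DL1 (1.98-fold). Cytosolic ribosomal protein genes rose in 33 of 72 and fell in 8 (34 and 8 adjusted over the list alone), led by RPL36 (2.45-fold) and RPL10 (2.04-fold). Glycolysis genes rose in 10 of 18 and fell in 2 (10 and 2 adjusted over the list alone), among them PFKL and PKM (1.85-fold each). Oxidative phosphorylation genes rose in 13 of 34 and fell in 6 (15 and 6), MYC target genes rose in 9 of 24 and fell in 1 (9 and 1), and cell cycle genes rose in 6 of 17 (7 adjusted over the list alone), led by TOP2A (3.11-fold) and CENPF (2.66-fold). These 7 calls were lost with an estimated correlation, each at adjusted p = 0.312. Immediate early genes rose in 4 of 25 and fell in 3 (4 and 3 adjusted over the list alone), with EGR1 2.50-fold higher. Their median was −0.007 and their mean 0.018 while camera gave a rise (adjusted p = 0.588 with an estimated correlation).

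The comparison of CD56neg with CD56dim cells called 3516 genes, 1848 higher and 1668 lower in CD56neg cells. Other genes with the largest rises were NELL2 (6.31-fold), the phosphatase gene INPP4B (5.25-fold), SPP2 (4.79-fold), DUSP4 (4.03-fold), the actin-binding protein gene COTL1 (3.96-fold), YBX3 (3.69-fold) and the titin gene TTN (3.61-fold). NELL2 had counts in only 24 of 40 CD56neg and 26 of 40 CD56dim libraries. Its mean levels, 2.44 ± 1.71 and 1.61 ± 0.73 log2 CPM (SD), lay closer than the fitted fold change. PCSK5 stood 6.10-fold higher (adjusted p = 7.86e-05), but its log2 fold change of 2.61 fell to 0.59 with limma-voom (adjusted p = 0.184) and 0.75 with DESeq2 (0.155). With limma-voom the calls on DUSP4 (1.07, adjusted p = 0.0916), CD8B (0.71, 0.264) and IGKC (1.13, 0.0958) also ended. Other genes with the largest declines were MYOM2 (5.41-fold), SPTSSB (4.67-fold), NPIPB12 (3.78-fold), the transcription factor gene BHLHE40 (3.49-fold), PTGDS (3.13-fold), RABGGTB (2.93-fold) and AP4B1 (2.80-fold). SPTSSB had only 22 counts in 4 of 40 CD56neg libraries and 122 in 25 of 40 CD56dim libraries. Both means (1.02 and 1.91 log2 CPM) lay near the floor, so the size of its fold is uncertain. The barcode sets differed here too. The share of calls that were higher was 52.6%, against 39.6% with RLE factors (1448 higher, 2210 lower), 41.6% with DESeq2 (1265 and 1774) and 33.3% with limma-voom (1361 and 2724), which moved the median of all genes to −0.14.

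ILCs lacked much of the NK cell program seen in CD56hi cells. Cytotoxic effector genes fell in 16 of 17 members (16 adjusted over the list alone, median −3.04, camera adjusted p = 1.16e-27), among them the granzyme B gene GZMB (26.8-fold), NKG7 (22.5-fold) and the granulysin gene GNLY (16.1-fold). CD56bright-associated genes fell in 13 of 18 and rose in 3 (14 and 3 adjusted over the list alone, camera adjusted p = 2.32e-12), with NCAM1 218-fold, SPTSSB 108-fold and IL12RB2 28.5-fold lower. Genes low in adaptive NK cells fell in 7 of 10 and rose in 2 (8 and 2 adjusted over the list alone, camera adjusted p = 1.43e-10). This list holds NK receptor genes, of which KLRF1 was 114-fold and NCR1, which encodes NKp46, 58.8-fold lower. KIR genes fell in 6 of 7 members (7 adjusted over the list alone, camera adjusted p = 7.94e-04), with KIR2DL4 130-fold lower. ILC-associated genes rose in 11 of 13 and fell in 1 (12 and 1 adjusted over the list alone, median 1.73, camera adjusted p = 7.56e-20). The prostaglandin dehydrogenase gene HPGD rose 18.4-fold, the costimulatory receptor gene CD28 10.3-fold and TNFRSF25 7.31-fold. ILC2-associated genes rose in 3 of the 4 members tested, of 14 in the list (3 adjusted over the list alone, camera adjusted p = 2.8e-04), led by PTGDR2 (5.60-fold).

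T cell markers rose beside the ILC-associated genes, in 11 of 16 members (12 adjusted over the list alone, median 1.46, camera adjusted p = 9.3e-12), with CD5 83.0-fold, CD3D 73.1-fold and THEMIS 32.9-fold higher in ILCs than in CD56hi cells. The 40 CD56hi libraries held only 22 counts of CD5, 93 of CD3D and 71 of THEMIS in all, so the size of these folds is uncertain. Monocyte and neutrophil markers rose in 8 of 15 (13 adjusted over the list alone), with adjusted p = 0.244 with an estimated correlation, and LYZ was 2.73-fold higher. Stem-like lymphocyte genes rose in 7 of 13 and fell in 1 (7 and 1 adjusted over the list alone), led by CD28 and CD27 (2.95-fold), with adjusted p = 0.111 with an estimated correlation. Glycolysis genes rose in 10 of 18 and fell in 1 (10 and 1), led by ENO2 (10.3-fold). Cytosolic ribosomal protein genes rose in 49 of 72 and fell in 3 (50 and 4 adjusted over the list alone), led by RPL10 (2.04-fold). Both had adjusted p = 0.0529 with an estimated correlation. Cell cycle genes fell in 10 of 17 and rose in 2 (11 and 2 adjusted over the list alone), with MKI67 8.82-fold lower and adjusted p = 0.111 with an estimated correlation. Mitochondrially encoded genes rose in 6 of 13 and fell in 1 (6 and 1), led by MT-ATP6 (1.86-fold), with adjusted p = 0.130 with an estimated correlation. Heat shock genes rose in 5 of 16 and fell in 3 (6 and 3), with DNAJB1 3.93-fold higher, a median of 0.227, a mean of −0.021 and adjusted p = 0.157 with an estimated correlation. Dendritic cell markers fell in 3 of the 4 members tested, of 12 in the list (3 adjusted over the list alone, camera adjusted p = 5.27e-05). These were GZMB, which is also a cytotoxic effector gene, IRF8 (15.3-fold) and TCF4 (2.44-fold).

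Of the 11224 genes, 4506 differed between ILCs and CD56hi cells, 1906 higher and 2600 lower in ILCs. Other genes with the largest rises were the metalloproteinase gene ADAM19 (12.5-fold), CD3G (11.9-fold), the kinase gene CAMK4 (11.8-fold), RTKN2 (10.7-fold), the T lineage transcription factor gene BCL11B (10.05-fold), PAG1 (7.01-fold), CD84 (6.86-fold) and MAF (6.84-fold). Other genes with the largest declines were the RNA-binding protein gene ZFP36 (48.3-fold), LGALS9B (42.5-fold), the sphingosine 1-phosphate receptor gene S1PR5 (35.9-fold), CHST2 (34.3-fold), IL18RAP (32.3-fold) and XCL2 (27.2-fold). RLE factors moved the median of all genes from −0.05 to −0.25 and gave 1172 higher and 4292 lower, DESeq2 gave 1069 and 3849, and limma-voom 1147 and 3418. The barcode sets also differed between these populations.

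ILCs against CD56dim cells, whose barcodes came from the same set, had the most genes called of the 5 comparisons, 6314, with 3052 higher and 3262 lower in ILCs. With limma-voom CD56hi against CD56dim cells had more (6669, against 6336 here), and ILCs were not tested against CD56neg cells. Stem-like lymphocyte genes rose in 13 of 13 members (13 adjusted over the list alone, median 3.04, camera adjusted p = 2.02e-17), with CCR7 110-fold, IL7R 44.96-fold and NELL2 37.9-fold higher. ILC-associated genes rose in 11 of 13 (12 adjusted over the list alone, camera adjusted p = 5.76e-16), led by the lymphotoxin beta gene LTB (72.4-fold) and KIT (48.2-fold). ILC2-associated genes rose in 3 of the 4 tested, of 14 in the list (3 adjusted over the list alone, camera adjusted p = 2.8e-05), with PTGDR2 22.3-fold and the transcription factor gene GATA3 5.17-fold higher. Cytosolic ribosomal protein genes rose in 64 of 72 and fell in 3 (64 and 3 adjusted over the list alone, median 1.02, camera adjusted p = 2.48e-57), led by RPL36 (5.80-fold) and RPL10 (4.88-fold), and held with an estimated correlation (adjusted p = 0.00689). Cytotoxic effector genes fell in 16 of 17 (16 adjusted over the list alone, median −4.09, camera adjusted p = 1.12e-26), with FGFBP2 130-fold, SPON2 113-fold and GZMH 62.0-fold lower. Mature CD56dim-associated genes fell in 13 of 15 (13 adjusted over the list alone, camera adjusted p = 1.24e-13), among them CX3CR1 (91.4-fold), S1PR5 (77.3-fold) and FCGR3A, which encodes CD16 (48.3-fold). KIR genes fell in 7 of 7 (7 adjusted over the list alone, camera adjusted p = 2.09e-06), with KIR3DL1 101-fold lower. Genes low in adaptive NK cells fell in 8 of 10 (8 fell and 1 rose adjusted over the list alone, camera adjusted p = 3.23e-07), led by KLRF1 (136-fold), and inhibitory receptor genes fell in 8 of 10 (8 adjusted over the list alone, camera adjusted p = 0.00164), led by CD244 (20.6-fold).

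T cell markers rose in 12 of 16 members and fell in 2 in this comparison (12 and 2 adjusted over the list alone), with CD5 16.7-fold and CD8B 15.5-fold higher, and adjusted p = 0.297 with an estimated correlation. Monocyte and neutrophil markers rose in 5 of 15 (5 adjusted over the list alone), with FCN1 3.16-fold higher and adjusted p = 0.511 with an estimated correlation. Glycolysis genes rose in 13 of 18 and fell in 4 (13 and 4, with ENO2 3.23-fold higher), and MYC target genes rose in 12 of 24 and fell in 3 (12 and 3, with SRM 2.83-fold higher). With an estimated correlation these had adjusted p = 0.297 and 0.273. Immediate early genes rose in 6 of 25 and fell in 7 (5 and 7 adjusted over the list alone). Their median was 0.088 and their mean −0.102, and the median became −0.185 with RLE factors, with adjusted p = 0.541 with an estimated correlation. Dendritic cell markers fell in 2 of 4 and rose in 1 (2 and 1 adjusted over the list alone), again through GZMB (41.6-fold) and IRF8 (14.1-fold), with adjusted p = 0.0557 with an estimated correlation. Further genes with the largest changes were RCAN3 (38.6-fold), FXYD7 (34.8-fold), CAMK4 (24.8-fold), INPP4B (20.7-fold), DUSP4 (19.2-fold) and FAM102A (15.3-fold) among those higher, and NCAM1 (80.3-fold), BNC2 (71.6-fold) and CHST2 (52.6-fold) among those lower. RLE factors moved the median of all genes from −0.02 to −0.31 and gave 1832 higher and 5012 lower, DESeq2 gave 1726 and 4854, and limma-voom 2072 and 4264.

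**Figure D3:**
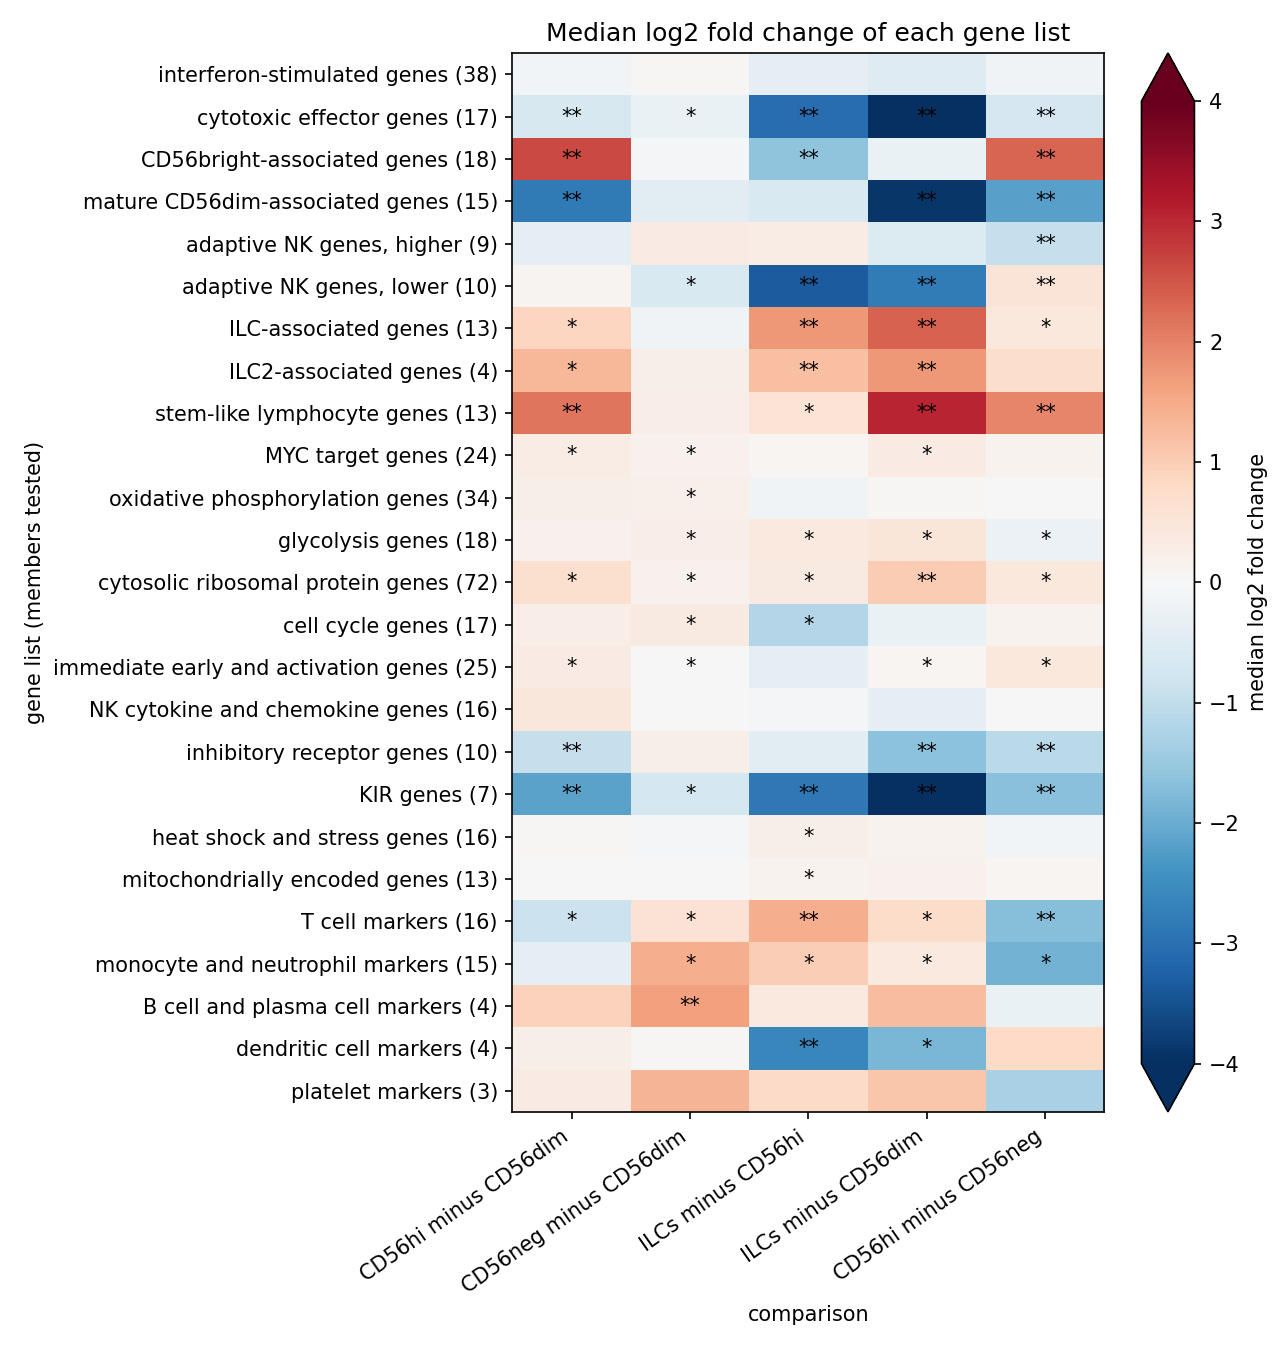
Median log2 fold change (colour) of the tested members of each of 25 gene lists (rows, members tested in parentheses) in the 5 comparisons (columns). 1 asterisk marks camera adjusted p below 0.05 and 2 asterisks a call that also held with an estimated correlation. Of the 5 comparisons, cytotoxic effector genes have their lowest median in ILCs against CD56dim cells (−4.09) and stem-like genes their highest (3.04). KIR genes are lower than cytotoxic effector genes there (median −4.875). The small medians of immediate early genes change sign with RLE factors and DESeq2 in ILCs against CD56dim cells, and with limma-voom in CD56neg against CD56dim cells.

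CD56hi and CD56neg cells, which also shared a barcode set, differed in 3852 genes, 2028 higher and 1824 lower in CD56hi cells. CD56bright-associated genes rose in 18 of 18 members (18 adjusted over the list alone, camera adjusted p = 2.97e-42), with SPTSSB 148-fold, KIT 73.2-fold and NCAM1 56.3-fold higher in CD56hi cells. Stem-like lymphocyte genes rose in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 1.95e-16), led by CCR7 (28.8-fold). Mature CD56dim-associated genes fell in 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.58e-31), with CX3CR1 13.2-fold lower. Cytotoxic effector genes fell in 11 of 17 and rose in 3 (12 and 4 adjusted over the list alone, camera adjusted p = 1.57e-07), led by FGFBP2 (7.72-fold). Inhibitory receptor genes fell in 7 of 10 and rose in 2 (7 and 2 adjusted over the list alone, camera adjusted p = 4.7e-06), with LAG3 50.5-fold and TIGIT 3.89-fold lower. KIR genes fell in 6 of 7 and rose in 1 (6 and 1, camera adjusted p = 0.00331). Genes high in adaptive NK cells fell in 6 of 9 and rose in 1 (6 and 1, camera adjusted p = 2.65e-05), led by LILRB1 (10.7-fold), and genes low in them rose in 6 of 10 (7 adjusted over the list alone, camera adjusted p = 2.65e-05), led by KLRC1 (4.30-fold). T cell markers fell in 13 of 16 (13 adjusted over the list alone, camera adjusted p = 5.54e-11), led by CD3D (24.9-fold). Monocyte and neutrophil markers fell in 15 of 15 (15 adjusted over the list alone), led by MNDA (5.27-fold), with adjusted p = 0.0557 with an estimated correlation. Cytosolic ribosomal protein genes rose in 58 of 72 (62 rose and 1 fell adjusted over the list alone, adjusted p = 0.25 with an estimated correlation), led by RPS28 (2.10-fold). Glycolysis genes fell in 8 of 18 (8 adjusted over the list alone, 0.0848), ILC-associated genes rose in 6 of 13 and fell in 3 (6 and 3, 0.0829), and immediate early genes rose in 12 of 25 and fell in 2 (14 and 2, 0.62), where the last value is each list's adjusted p with an estimated correlation. The long noncoding RNA gene MIAT was 13.1-fold lower. With limma-voom the split was 2572 higher and 1334 lower, and the median of all genes moved from 0.03 to 0.12.

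Interferon-stimulated genes passed camera in none of the 5 comparisons in the fit of all libraries without a block and with the preset correlation. Between CD56hi and CD56dim cells 6 of 38 rose and 9 fell (3 and 9 adjusted over the list alone), between CD56neg and CD56dim cells 4 rose and 4 fell (4 and 4), and between CD56hi and CD56neg cells 4 rose and 11 fell (5 and 12). In ILCs 2 rose and 15 fell against CD56hi cells (2 and 16) and 3 rose and 17 fell against CD56dim cells (3 and 17), with camera adjusted p = 0.0626 and 0.0709. With fry the list was called lower in ILCs in both (adjusted p = 1.06e-05 and 1.3e-06). Camera also called it in both with the barcode number as a block, as reported in the closing section. Without the libraries richest in T cell or monocyte markers the list passed for CD56neg against CD56dim cells (camera adjusted p = 0.0271). The lists of NK cytokine and chemokine genes and platelet markers passed camera in none of the comparisons in that fit either. NK cytokine and chemokine genes rose in 9 of 16 and fell in 6 between CD56hi and CD56dim cells (9 and 6). Fry called them lower in ILCs than in CD56hi cells (4 rose and 7 fell, fry adjusted p = 2.25e-04) and CD56dim cells (5 and 7, 0.00268). Platelet markers rose in 3 of 3 between CD56neg and CD56dim cells (3 adjusted over the list alone, camera adjusted p = 0.106). That last list passed there with fry (adjusted p = 0.0468) and with camera and the block. Between ILCs and CD56hi cells platelet markers rose in 1 of 3 (1 adjusted over the list alone) and passed without the marker-rich libraries (camera adjusted p = 0.0442, against 0.0509 with them). Fry called platelet markers higher there (adjusted p = 9.08e-04) and in ILCs against CD56dim cells (0.00508), and lower in CD56hi than in CD56neg cells (0.00795).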

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

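All settings here were chosen after seeing the data, because the planned comparisons within HIV-1 groups, and their alternatives, could not be run on libraries without an HIV-1 group. Counts of genes past the threshold stayed within 1.5 times the reported ones except in 6 cases. Thinning to 100000 counts left 3003 genes to test and called 1521 for CD56hi against CD56dim cells, 925 for CD56neg against CD56dim, 1354 for ILCs against CD56hi, 1811 for ILCs against CD56dim and 1115 for CD56hi against CD56neg. Without a low-count filter, with 44859 genes tested, ILCs against CD56hi gave 6970. At most 1 gene called in both a setting and the reported fit had the opposite direction. With the 10 libraries richest in each kind of marker left out per population, the 5 comparisons called 5249, 2697, 3829, 5540 and 3067. Of 260 results for named genes, none turned its direction in a setting that could test it. Limma-voom and DESeq2 ended 7 calls each, the marker-rich setting 6, no filter 3, RLE factors 1 and the block 1. Thinning ended 3 and left 152 as they were, and the other results did not pass its count filter, so they were not tested at equal depth. RLE factors, no filter and DESeq2 each added 1 call, TCF7 in ILCs against CD56hi cells. RUNX3 in CD56neg against CD56dim cells had adjusted p = 0.234 without a filter and 0.132 without the marker-rich libraries. MYC levels near the floor moved with the prior count, to 0.57 in CD56dim and 0.46 in CD56neg cells at 0.5. Camera called 12 lists for CD56hi against CD56dim cells, 12 for CD56neg against CD56dim, 15 for ILCs against CD56hi, 15 for ILCs against CD56dim and 14 for CD56hi against CD56neg. With an estimated correlation 35 of these camera calls on lists were lost. With fry 8 were lost, and 27 were added in the direction that camera gave.

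The labels give replicate numbers, and the columns carry barcode numbers in their place. With the barcode number (41 taken as 1) as a block, the counts were 6240, 3844, 4816, 6575 and 4293 in the order above, and the block ended the call on PCSK5 in CD56neg against CD56dim cells (0.50, adjusted p = 0.266). Among lists the block ended 1 camera call, immediate early genes in CD56neg against CD56dim cells (adjusted p = 0.624), and added 6. These were interferon-stimulated genes in ILCs against CD56hi (adjusted p = 0.0244) and against CD56dim cells (0.0274), platelet markers (0.0326) and mature CD56dim-associated genes (0.0206) in CD56neg against CD56dim cells, B cell and plasma cell markers in CD56hi against CD56dim cells (0.037) and mitochondrially encoded genes in ILCs against CD56dim cells (0.00727). A correlation of deviations over 0.1 was found in 35 of 38 same-number pairs of CD56hi and CD56dim libraries, 32 of 39 of CD56hi and CD56neg, 27 of 34 of CD56hi and ILCs, 32 of 37 of CD56dim and CD56neg, 31 of 34 of CD56dim and ILCs and 13 of 33 of CD56neg and ILCs. The mean correlation exceeded that of other numbers in each of the 6 (permutation p = 1e-05 each), so libraries of 1 number do resemble each other. No population pair had all of its pairs over 0.1, the bar set for a paired fit, so the reported fit stayed without the block, and the likeness is a hint from the data and not the design.

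Groupings of libraries by chance were weighed with tests fixed before they were run. In each comparison 1 of 100 splits of the 80 libraries, the real one, reached the real count. A random grouping of single libraries is thus argued against, at a resolution of 1 in 100. The splits ignored the likeness of same-number libraries and cannot tell populations from barcode sets or pools. The highest other split called 408 genes for CD56hi against CD56dim cells (real 5877), 33 for CD56neg against CD56dim (3516), 1364 for ILCs against CD56hi (4506), 147 for ILCs against CD56dim (6314) and 185 for CD56hi against CD56neg (3852).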

Other observations

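Of the tests below, those on cross-talk, on a shared HIV-1 group, on depth and on the co-variation of markers were chosen only after the patterns had been seen. Those on ERAP2 and AREG were written before their results were seen.

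The mean level of 38 interferon-stimulated genes varied widely between libraries of 1 population. It ran from 3.63 to 6.87 log2 CPM in CD56hi cells (median 5.13, 40 libraries), 4.53 to 7.28 in CD56dim cells (median 5.09, 38 libraries), 3.56 to 7.12 in CD56neg cells (median 4.84, 39 libraries) and 3.26 to 6.64 in ILCs (median 4.44, 34 libraries). Libraries of different populations with the same barcode number (41 taken as 1) had similar levels. Over 38 pairs of CD56hi and CD56dim libraries Pearson's r was 0.844 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Spearman's rho 0.728 (p = 2e-05, adjusted 4e-05 over 6 population pairs), and r was 0.813 without the 2 farthest libraries. Over 37 pairs of CD56dim and CD56neg libraries r was 0.883 (adjusted p = 1e-05) and rho 0.688 (adjusted p = 4e-05), with r = 0.800 without the 2 farthest. For CD56neg cells and ILCs r was 0.589 (adjusted p = 5e-04), but rho was 0.288 (adjusted p = 0.104) and r 0.294 without the 2 farthest libraries, on which that relation rests.

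Libraries with the same barcode number also deviated together across 4491 genes, with a mean correlation of deviations from 0.117 (CD56neg cells and ILCs) to 0.285 (CD56hi and CD56dim cells) against −0.006 to 0.000 for other numbers. Cross-talk between libraries that carry the same barcode is argued against, since the 4 population pairs whose barcodes lie 40 apart had a mean correlation of 0.204. A shared HIV-1 group alone is argued against too, since it would give at most about 1 in 10 best matches to the own number, and the lowest exact 95% lower bound over the 6 population pairs was 30.09%. A candidate explanation is that 1 number marks 1 person: ERAP2, a peptidase gene whose blood level depends on a common inherited variant, had rho = 0.791 between CD56hi and CD56dim libraries of 1 number (r = 0.793, permutation p = 1e-05 for both, 38 pairs, r = 0.789 without the 2 farthest libraries). The labels do not state this, and shared handling of a person's cells stays open beside it.

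Monocyte and neutrophil markers were higher in CD56neg than in CD56dim libraries. Lower depth of the CD56neg libraries was weighed on the unscaled counts of the 13 risen markers, which fewer reads cannot raise. Their median log2 ratio of mean unscaled counts, CD56neg over CD56dim cells, was 1.417. Its 95% range was 0.203 to 2.606 over 10000 resamplings of the libraries, and the log2 ratio of the library totals was −0.028. Unscaled counts were higher for all 13. These markers had been picked as higher in the same libraries, and the mean library totals were nearly equal. A rise in unscaled counts was therefore nearly fixed in advance and cannot decide on depth. After thinning, 3 of the 13 could be tested. These 3 (FCN1, LYZ and VCAN) remained higher, with a median log2 fold change of 2.03 before and 2.07 after. That argues against lower depth for these 3 markers only. The 15 markers rose and fell together over 39 CD56neg libraries (median pairwise rho = 0.692, against 0.026 for random sets of 15 genes), in line with a varying share of monocytes, a hypothesis. LYZ stood at 8.29 and FCN1 at 7.44 log2 CPM, but S100A9 at 3.46 and CST3 at 4.59 did not pass, and a change within the CD56neg cells was not tested. No source used here describes a gate against monocytes.

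T cell markers were higher in ILC than in CD56hi libraries, and the 16 markers co-varied over 34 ILC libraries (median pairwise rho = 0.531, against 0.029 for random sets), which is consistent with a varying share of T cells, a hypothesis. TRBC2 stood at 8.94, CD3E at 6.52, TRAC at 6.43 and CD3D at 5.45 log2 CPM in ILCs, though CD3E did not differ from CD56hi cells (0.30, edgeR adjusted p = 0.288). Lower depth of the ILC libraries is argued against for the 11 risen markers as a set, since fewer reads cannot raise unscaled counts. Their median log2 ratio of mean unscaled counts, ILCs over CD56hi cells, was 1.625 (95% range 0.898 to 2.261 over 10000 resamplings of the libraries), against −1.771 for the library totals. Unscaled counts were higher for 7 of the 11, and for the other 4 depth was not excluded singly. This test replaced one on thinned counts, which left only 2 of the 11 to test, both of which remained higher (median log2 fold change 1.33 before and 1.39 after). Transcription of these genes in the ILCs themselves was not tested, and CD3E is also in the list of genes high in adaptive NK cells.

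AREG was tested across libraries within each population against the mean of the immediate early genes, under the hypothesis that AREG follows recent activation, and against TCF7, 8 relations in all. The immediate early hypothesis predicted a positive relation, and r was −0.374 in CD56hi cells (permutation p = 0.0169, adjusted 0.0678, rho = −0.229 with adjusted p = 0.357, r = −0.345 without the 2 farthest libraries) and −0.504 in CD56dim cells (p = 0.001, adjusted 0.00792, rho = −0.345 with adjusted p = 0.136, r = −0.439 without the 2 farthest). In CD56neg cells r was −0.101 (adjusted p = 0.86, rho = −0.083, r = −0.207 without the 2 farthest), and the upper 95% bounds in these 3 populations (−0.071, −0.220 and 0.221) exclude the predicted 0.3. In ILCs r was 0.034 (adjusted p = 0.972, rho = 0.128, r = 0.177 without the 2 farthest), with bounds from −0.308 to 0.368 that leave it open. With TCF7, r was −0.205 in CD56hi cells, 0.006 in CD56dim cells, −0.288 in CD56neg cells and −0.055 in ILCs (rho = −0.217, 0.001, −0.362 and −0.111, lowest adjusted p = 0.206 for r and 0.136 for rho, r = −0.164, −0.032, −0.292 and −0.173 without the 2 farthest), so no relation with TCF7 passed and the question stays open. With library depth held fixed, r with TCF7 was −0.227, 0.018, −0.187 and −0.309 in the same order (95% bounds in ILCs −0.590 to 0.039), and r with the immediate early genes was −0.373, −0.507, −0.028 and 0.015, with an upper bound of 0.294 in CD56neg cells. The ILC relation with TCF7 thus depends on how depth is handled.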
